A study of Vitis vinifera with 18 samples.

How the data were processed

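Total RNA from berry skin of Muscat and Neutral hybrids was sequenced by the authors on a DNBSEQ-T7 instrument, in 18 libraries from 2 types, 3 stages and 3 replicates. The values used are FPKM per gene, made by the authors and deposited as 1 table with 2 decimals, and the values fit that unit (FPKM totals of 1065928 to 1193944 per library). Read trimming, alignment, the genome build and the treatment of reads shared between gene copies are not given in the sources used here. All 25187 gene names of the table were found in the annotation of assembly GCF_030704535.1 ASM3070453v1, 25029 by symbol and 158 by locus tag, and that table was used for names, synonyms and the order of genes. It gives a symbol or synonym other than a number for 349 nuclear genes. It also names 84 plastid-encoded and 74 mitochondrion-encoded genes. Genes of close families (PR10, stilbene synthase, chalcone synthase, chitinase) may share reads, and their single values are uncertain in that respect.

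FPKM values were taken to log2 after adding 1, so every fold change given is on the log2(FPKM + 1) scale and shrinks for scarce genes. Genes with at least 1 FPKM in at least 3 of 18 libraries were kept, 15981 in all. A linear model with 1 mean for each of the 6 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with a trend), with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05 on the adjusted p-value. The table holds FPKM values, so no count model was used, and the fit gives no weight to depth. Muscat was compared with Neutral at each stage and on average over the 3 stages, consecutive stages within each type, and an F-test asked whether the course over the stages differs between the types. The comparisons, the test, the expression minimum, the threshold, the alternatives and the rule for naming genes were chosen before the data were examined. In text, ± after FPKM gives the SD over 3 libraries and ± after a log2 value its SE from the model. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

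Genes are named by a rule. For each comparison it takes the 10 genes with the largest absolute log2 change among those past the threshold whose groups do not overlap and whose mean log2 value is at least 2, and for each list up to the 2 highest and 2 lowest members past the threshold. Of the genes without a name, at most 2 each way are printed per comparison. After the values were seen, the list genes named were mostly limited to changes of 2-fold or more. The rule also provided for every gene of the methylerythritol phosphate pathway and of the monoterpene synthases, the subject of the series title, and this part could not be carried out. The 24 lists fixed beforehand rest on gene descriptions, the tables hold symbols without descriptions, and 0 of the 24 lists found 3 or more genes among symbols and synonyms. No monoterpene gene is therefore named or tested as a list.

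In their place, 24 lists were built from symbols and synonyms after the data were seen, so they are not independent of the data: anthocyanin and flavonol synthesis, proanthocyanidin synthesis, flavonoid regulators, stilbenes and phenylpropanoid entry, sesquiterpene synthases, carotenoids and apocarotenoids, lipoxygenase and alcohol dehydrogenase, sugar transport and cleavage, aquaporins, pathogenesis-related, ripening-induced GRIP, CBL and CIPK calcium signalling, copper transporters, MADS-box, MLO, organic acid and amino acid metabolism, S-adenosylmethionine, antioxidant, gibberellin, germin-like, heat shock and ER chaperone, seed and flower identity (another tissue), plastid-encoded photosynthesis, and mitochondrion-encoded genes (library quality). The 22 lists with at least 3 tested genes were compared with all other genes by camera with a correlation of 0.01, adjusted over 88 tests for the type comparisons and 88 for the stage comparisons. The result with a correlation estimated from the data stands beside each call, and fry was run as a test of direction on balance. Adjusted p-values over a list alone were also computed.

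Depth was read from the table. In organelle genes with a span under 350 bp, low FPKM values are multiples of 1 fragment, and the fragment total that makes at least 85.0% of the values below 12 fragments whole (within 0.03 fragments) was searched for each library. These settings were set while looking at the values, and the result is given as at least 15.3 to 60.5 M (mega) fragments, with 88.0% to 100.0% of the values whole. On simulated libraries the search was tested on 18 sizes and found 18 within 2 percent. Replicates were then checked against sampling noise in 85 short nuclear genes with a span below 900 bp, 0.9 of whose values had to be whole. The residual SD of the model had a median of 0.0767 log2 units with 12 residual degrees of freedom and 5.53 added by the prior.

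The pipeline was tested on simulated data with 15981 genes and 200 changed genes per comparison. Changes of 1 log2 unit were recovered in 92.5% to 100.0% of genes over the 9 comparisons and changes of 0.5 in 70.1% to 97.0%, with at most 14 unchanged genes called. The simulated noise was independent between genes, without shifts between groups, and far fewer genes changed than were called in the data. The number of false calls in the data cannot be read from it. The alternatives were a pseudocount of 0.1, no expression minimum, scaling to a common upper quartile, the replicate number as a block, a model of the compared groups alone, a 2-fold minimum and each library left out in turn. Nothing in the table was left out apart from genes below the minimum.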

Results

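Gene expression was measured by RNA sequencing in the berry skin of Muscat and Neutral grape hybrids (Vitis vinifera) from a cross of 'Midknight Beauty' with 'Red Globe'. Muscat grapes are known for an aroma rich in monoterpenes, which neutral grapes largely lack. Skin was sampled at 3 stages of the E-L scale of grapevine development, E-L 34, when berries begin to soften, E-L 37, shortly before ripeness, and E-L 38, at harvest ripeness. Each of the 6 groups of type and stage held 3 libraries, 18 in all. The deposited table gave FPKM values for 25187 protein-coding genes. Between 14368 and 14880 genes per library reached 1 FPKM, and 15981 genes entered the tests.

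The sequencing depth was read from the steps between low FPKM values and came to at least 28.2 to 51.9 M (mega) fragments per library in Muscat E-L 34, 36.1 to 51.3 in Muscat E-L 37 and 16.3 to 21.4 in Muscat E-L 38. In Neutral it was at least 15.7 to 20.9 M at E-L 34, 15.3 to 18.8 at E-L 37 and 31.2 to 60.5 at E-L 38. Depth thus differed between the groups compared. The class IV chitinase gene CHI4D had the highest FPKM in all libraries of Muscat E-L 34, Neutral E-L 34 and Neutral E-L 38, and the thaumatin-like gene TL3 in Neutral E-L 37. In Muscat E-L 37 and E-L 38 it was the unnamed LOC100257132. This gene, LOC100257132, reached 99160 ± 8401 FPKM (SD, n = 3) in Muscat E-L 37. The 10 most abundant genes took 11.65% to 22.74% of the FPKM of a library. Plastid-encoded genes took 0.0025% to 0.0153% and mitochondrion-encoded genes 0.0032% to 0.0101%. The plastid share was lowest at E-L 34 and highest at E-L 38 in both types. Replicates lay close together, with Pearson correlations of log2 values across genes from 0.99588 to 0.99902. Over 11 to 37 short genes per pair, the fragment counts of the 18 replicate pairs agreed about as well as sampling noise allows (chi-square per degree of freedom 0.693 to 1.539), against 5.38 and 8.94 between libraries of different stages. These short genes were chosen on values of few fragments, so the check says little about abundant genes. In Neutral E-L 37, GER7 spread widely (15526.6, 12498.2 and 12677.3 FPKM), whereas LOXA did not (92.74, 90.2 and 92.56 FPKM). No pair stood out as a repeat of the same library. Nothing in the labels says that replicates came from separate vines or harvests. The p-values measure only the spread between these samples, which may be technical.

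**Figure D1:**
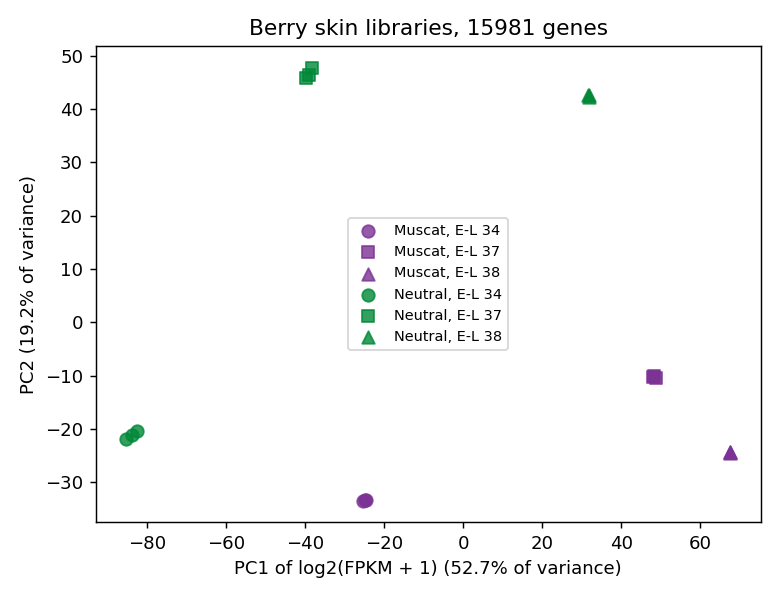
The 18 libraries on the first principal components of log2(FPKM + 1) over 15981 genes, with the share of variance of each component on its axis, types by colour and stages by marker shape. PC1 holds 52.7% and PC2 19.2% of the variance, and the 3 replicates of each group lie together, apart from the other 5 groups.

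At E-L 34, the comparison of Muscat with Neutral skin asked how the types differed when berries began to soften, and the largest difference among the genes named was in GRIP61, a gene named for its induction in ripening grape. GRIP61 had 14397 ± 576 FPKM (SD, n = 3) in Muscat and 0.977 ± 0.549 in Neutral, a log2(FPKM + 1) difference of 12.86 ± 0.12 (SE, adjusted p = 1.89e-22). Of 13 anthocyanin and flavonol genes 10 were lower in Muscat, among them UFGT, which adds glucose to anthocyanidins (16.5 ± 0.656 against 70.3 ± 7.78 FPKM, log2 difference -2.02 ± 0.07). Another was FAOMT, which methylates anthocyanins (4.61 ± 0.641 against 31.7 ± 0.478, -2.55 ± 0.09). BiP (LOC100263033), a chaperone of the endoplasmic reticulum, was higher in Muscat (114 ± 0.401 against 8.67 ± 0.466 FPKM, 3.57 ± 0.07). The germin-like gene GER7 was lower (14.5 ± 1.03 against 330.0 ± 7.57 FPKM, -4.42 ± 0.06).

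Of the 13 anthocyanin and flavonol genes tested, 0 were higher in Muscat, 10 were lower and 3 did not pass. The same number, 10, passed when adjusted over the list alone. The list was lower than other genes by camera (adjusted p = 0.0218), a call lost at adjusted p = 0.0903 with an estimated correlation. Among the flavonoid regulators, MYBPA1, an activator of proanthocyanidin synthesis (11.6 ± 0.251 against 39.4 ± 0.610 FPKM, log2 difference -1.68 ± 0.09), and the bHLH gene MYC1 (-1.41 ± 0.06) were lower. The MybA-type gene LOC100853472 was higher (226 ± 10.63 against 42.5 ± 3.15 FPKM, 2.39 ± 0.05). In all, 2 of 10 regulators were higher, 7 lower and 1 did not pass. Both proanthocyanidin genes tested were lower, LAR2 by -1.78 ± 0.07 and ANR by -0.86 ± 0.13. The MADS-box genes had 7 of 8 members lower and 0 higher (camera adjusted p = 0.0387, and adjusted p = 0.322 with an estimated correlation). MADS3 differed by -1.28 ± 0.11 and AG by -1.21 ± 0.03. MFT, which belongs to the list of seed and flower identity genes, was also lower in Muscat (2.11 ± 0.121 against 18.6 ± 1.22 FPKM, -2.66 ± 0.08), while the other two members tested did not pass. Mitochondrion-encoded genes, a list kept for library quality, had 12 of 29 tested members (of 74 measured) higher and 1 lower (adjusted p = 0.308).

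Aquaporins went both ways at E-L 34, with 5 of 10 higher and 5 lower. The tonoplast gene TIP1;1 (-2.66 ± 0.09) and the plasma membrane gene PIP1;1 (-2.04 ± 0.10) were lower, and PIP2;2 (1.38 ± 0.03) and PIP2 (1.08 ± 0.09) were higher. Sugar transport and cleavage genes were also split, 9 higher and 7 lower of 17. Of the hexose transporter genes HT5 was lower (-1.88 ± 0.04) and HT6 higher (1.27 ± 0.04), the cell wall invertase CWINV was lower (-1.87 ± 0.05) and TMT2 higher (1.33 ± 0.06). Of 16 pathogenesis-related genes, 11 were lower and 4 higher. The extremes were PR10.4 by -4.04 ± 0.08 and PR1 by -2.79 ± 0.10 at one end and the thaumatin-like TL1 by 1.08 ± 0.05 at the other. The carotenoid genes BCH1, a beta-carotene hydroxylase (-1.99 ± 0.08), and CCD4b (LOC100252859), a carotenoid cleavage dioxygenase (-1.09 ± 0.06), were lower. In that list, 5 of the 9 members were higher and 3 lower. Among smaller lists, the gibberellin 2-oxidase gene GA2ox6 (LOC100258946, -2.23 ± 0.07), the glutamate dehydrogenase gene GDHB (-1.75 ± 0.08) and the calcium signalling kinase gene CIPK08 (-1.75 ± 0.06) were lower. So were MLO11 (-1.43 ± 0.07), the S-adenosylmethionine synthetase gene METK3 (-1.06 ± 0.05) and the ascorbate peroxidase gene APX (-1.04 ± 0.06). The copper transporter CTR2 (1.61 ± 0.13), the lipoxygenase LOXA (1.37 ± 0.02) and GRIP31 (1.59 ± 0.04) were higher. The unnamed LOC100253073 was higher (5.06 ± 0.13), and LOC100263665 (-5.12 ± 0.09) and LOC100253046 (-4.81 ± 0.04) were lower.

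By limma, 12790 of 15981 genes passed at E-L 34, 6474 higher and 6316 lower in Muscat. Of these, 2536 differed by 2-fold or more, 999 higher and 1537 lower. The 3 libraries of one type lay wholly above those of the other for 81.5% of genes, where chance gives 10%. Depth differed between these groups, and PR10, chitinase, stilbene synthase and chalcone synthase genes have close copies among which reads can be shared.

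At E-L 37, the question was how the types differed during ripening, and 2 chalcone synthase genes were higher in Muscat. CHS2 (LOC100232843), a chalcone synthase gene for the entry step of flavonoid synthesis, had 287 ± 5.74 FPKM (SD, n = 3) in Muscat and 72.9 ± 7.70 in Neutral (log2 difference 1.97 ± 0.05, SE, adjusted p = 1.14e-16). CHS1 (LOC100263443) had 30.4 ± 1.72 against 5.49 ± 0.182 FPKM (2.27 ± 0.06). ADH1 and ADH2, genes of alcohol dehydrogenases, which interconvert aldehydes and alcohols, were lower in Muscat, ADH1 with 13.3 ± 0.379 against 169 ± 5.80 FPKM (-3.57 ± 0.04) and ADH2 with 91.6 ± 3.41 against 773 ± 46.1 FPKM (-3.06 ± 0.04). In contrast, the lipoxygenase gene LOXA was higher in Muscat (608 ± 4.07 against 91.8 ± 1.42 FPKM, 2.71 ± 0.02). The lipoxygenase and alcohol dehydrogenase list had 3 of 8 genes higher and 5 lower (camera adjusted p = 0.139). GER7 reached 13567 ± 1699 FPKM in Neutral and 518 ± 19.96 in Muscat (-4.70 ± 0.06).

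Of 16 pathogenesis-related genes, 13 were lower in Muscat and 2 higher (camera adjusted p = 0.000454, and adjusted p = 0.0903 with an estimated correlation), with a median 1.59 below that of all genes on the log2 scale. The chitinase gene LOC100232985 (4.14 ± 0.317 against 133 ± 6.60 FPKM, -4.71 ± 0.08) and G1, listed under the synonym Glub (209 ± 10.99 against 3249 ± 173 FPKM, -3.95 ± 0.06), were lower. PR10.7 (52.2 ± 1.56 against 1.19 ± 0.554 FPKM, 4.64 ± 0.12) and PR10.5 (3.19 ± 0.05) were higher. CBL and CIPK calcium signalling genes had 15 of 25 members lower and 5 higher (camera adjusted p = 0.0394, and adjusted p = 0.278 with an estimated correlation). CIPK08 (-1.57 ± 0.06) and CBL04 (-1.44 ± 0.10) were lower and CIPK15 (LOC100259329) was higher (2.46 ± 0.06). In the anthocyanin and flavonol list, 9 of 13 genes were higher, 3 lower and 1 did not pass. The camera test did not call it (adjusted p = 0.254). CHS3 was among the lower ones (-0.69 ± 0.04), so chalcone synthase genes went both ways. MYC1 (1.91 ± 0.06) and MYBC2-L1 (1.69 ± 0.04) were higher and MYBPA1 was lower (1.62 ± 0.249 against 28.1 ± 2.43 FPKM, -3.48 ± 0.09). Of 10 regulators, 8 were higher and 2 lower. Of 29 mitochondrion-encoded genes, 16 were higher and 1 lower (adjusted p = 0.509).

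Among carotenoid genes at E-L 37, the zeaxanthin epoxidase ZEP (23.0 ± 1.69 against 4.70 ± 0.342 FPKM, 2.07 ± 0.06) and the cleavage dioxygenase CCD1 (460.1 ± 23.3 against 177 ± 4.02 FPKM, 1.37 ± 0.04) were higher in Muscat. NCED2, of the enzyme family that leads to abscisic acid (-2.28 ± 0.07), and BCH1 (-1.94 ± 0.08) were lower, with 4 higher and 5 lower of 9. Aquaporins had 4 members higher and 5 lower of 10. At the ends lay PIP2;3 (2.78 ± 0.05) and TIP1;2 (2.1 ± 0.06) against TIP1;1 (-3.22 ± 0.09) and TIP2;1 (-2.19 ± 0.08). The stilbene synthase gene VINST1 (-1.54 ± 0.08) and MYB14, an activator of stilbene synthases (-1.64 ± 0.06), were lower, and 4CL was higher (1.08 ± 0.06). There were 5 lower and 1 higher of 6 in the list of stilbenes and phenylpropanoid entry. Sugar transport genes were split, 8 higher and 8 lower of 17. HT6 (1.87 ± 0.04) and HT2 (LOC100232961, 1.73 ± 0.05) were higher, and the sucrose transporter VVSUC27 (-2.07 ± 0.09) and HT5 (-1.87 ± 0.04) lower. Of the ripening-induced GRIP genes, GRIP31 (1.28 ± 0.04) and GRIP32 (1.15 ± 0.07) were higher and GRIP68 (-2.14 ± 0.06) and GRIP61 (-1.05 ± 0.12) lower, 4 higher and 6 lower of 11. The 3 gibberellin genes tested were higher, GA2ox6 by 2.02 ± 0.07, while 3 of 4 germin-like genes and 5 of 7 MLO genes were lower, MLO11 by -1.92 ± 0.07. METK4 (1.61 ± 0.05) and METK3 (-1.18 ± 0.05) went opposite ways among 5 S-adenosylmethionine genes, 2 higher and 3 lower. The unnamed LOC100261940 (-7.93 ± 0.09) and LOC100243529 (-6.99 ± 0.07) were far lower in Muscat, and LOC100267971 (6.07 ± 0.07) and LOC100245734 (5.82 ± 0.05) far higher.

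At E-L 37, limma called 13306 genes, 8293 higher and 5013 lower in Muscat. Of them 3133 differed by 2-fold or more (1604 higher, 1529 lower). After scaling to a common upper quartile, 7182 were higher and 5812 lower, and at 2-fold 1331 higher and 1754 lower. The libraries of the types did not overlap for 82.0% of genes against 10% by chance. The median of all genes lay 0.17 above 0 on the log2 scale, and 0.07 above after scaling to a common upper quartile, a shift of 0.102. The signs of the named genes that differed by 2-fold or more were the same after that scaling.

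**Figure D2:**
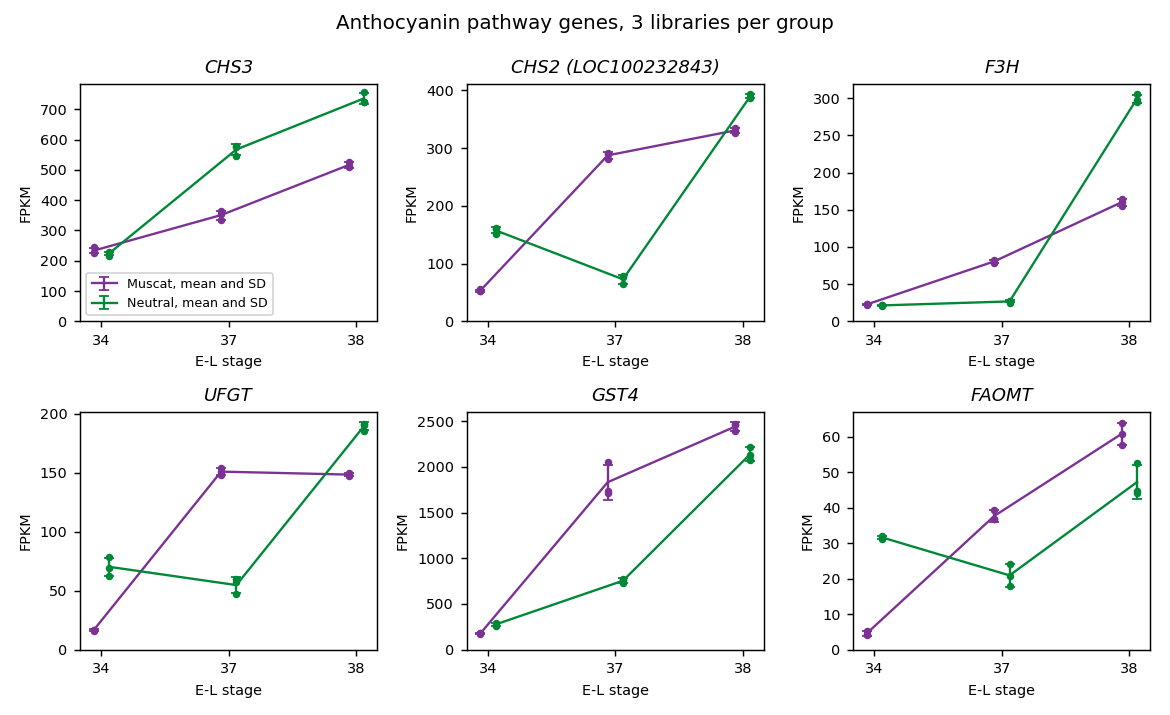
FPKM of 6 anthocyanin genes by stage and type, with points for single libraries and lines for group means, and bars that give SD over 3 libraries. UFGT, FAOMT and CHS2 (LOC100232843) lie higher in Neutral at E-L 34 and higher in Muscat at E-L 37.

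At E-L 38, harvest ripeness, several defence genes and a stilbene synthase gene were lower in Muscat than in Neutral skin. G1 had 7.59 ± 0.265 FPKM (SD, n = 3) in Muscat and 566 ± 37.7 in Neutral (log2 difference -6.04 ± 0.06, SE, adjusted p = 3.56e-22). PR10.4 had 0.233 ± 0.140 against 20.2 ± 0.884 FPKM (-4.11 ± 0.08). The stilbene synthase gene LOC100217471 (24.3 ± 1.69 against 137 ± 2.57 FPKM, -2.45 ± 0.05) and the caffeoyl-CoA methyltransferase gene LOC100233087 (8.56 ± 0.274 against 92.2 ± 2.02 FPKM, -3.28 ± 0.06) were lower as well. GRIP61 was again higher in Muscat (2801 ± 59.4 against 195 ± 4.82 FPKM, 3.84 ± 0.12). So were GRIP68 (574 ± 19.4 against 50.8 ± 0.498 FPKM, 3.47 ± 0.06) and CCD4b (LOC100252859, 31.5 ± 0.970 against 4.53 ± 0.204 FPKM, 2.55 ± 0.06).

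All 6 genes of stilbenes and phenylpropanoid entry were lower in Muscat (camera adjusted p = 0.000454, and adjusted p = 0.0846 with an estimated correlation). The pathogenesis-related list had 12 of 16 genes lower and 3 higher (adjusted p = 0.000454, and adjusted p = 0.0903 with an estimated correlation). PR10.5 was higher by 1.43 ± 0.05. In the lipoxygenase and alcohol dehydrogenase list, 6 of 8 genes were lower and 2 higher (adjusted p = 0.031, and adjusted p = 0.109 with an estimated correlation). LOXO (37.1 ± 0.729 against 194 ± 1.11 FPKM, -2.35 ± 0.03) and ADH1 (-2.36 ± 0.04) were lower and LOXA (401 ± 5.16 against 66.9 ± 1.04 FPKM, 2.56 ± 0.02) was higher. Aquaporins had 7 of 10 genes higher and 1 lower (adjusted p = 0.193), with PIP2 (3.60 ± 0.09) and PIP2;3 (1.96 ± 0.05) at the top. Anthocyanin and flavonol genes were split again, 4 higher and 8 lower of 13 (adjusted p = 0.0685). The ends were the flavonol synthase FLS1 by 1.55 ± 0.07 and the chalcone isomerase CHI by -1.03 ± 0.03. Mitochondrion-encoded genes had 2 of 29 higher and 9 lower (adjusted p = 0.26).

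ZEP (1.57 ± 0.06) was higher and BCH1 (-1.21 ± 0.08) lower among carotenoid genes at E-L 38. HT5 was lower (14.5 ± 0.230 against 115 ± 1.96 FPKM, -2.91 ± 0.04), while 6 of 17 sugar transport genes were higher and 8 lower. LOC100853472 (1.52 ± 0.05) and MYBA6 (1.23 ± 0.11) were higher among regulators, of which 7 of 10 were higher and 2 lower. CIPK16 (1.84 ± 0.06), CIPK08 (1.15 ± 0.06), GDHB (1.40 ± 0.08) and the heat shock gene HSP101 (1.33 ± 0.05) were higher. The gibberellin 20-oxidase gene GA20ox1 (LOC100257500, -1.96 ± 0.12), the glutamine synthetase gene LOC100246404 (-1.41 ± 0.03), LOC100267554 of the MLO family (-1.33 ± 0.03) and the thioredoxin h gene LOC100250566 (-1.15 ± 0.11) were lower. Of the unnamed genes, LOC100263489 (5.68 ± 0.09) and LOC100252964 (4.67 ± 0.13) were higher, and LOC100247990 (-7.48 ± 0.08) and LOC100242852 (-5.82 ± 0.08) lower. By limma, 11964 genes passed, 7648 higher and 4316 lower, and 6613 higher and 5042 lower after scaling to a common upper quartile. There were 972 higher and 1040 lower by 2-fold or more, 2012 together. The types did not overlap for 81.4% of genes against 10% by chance.

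Averaged over the 3 stages, the lipoxygenase gene LOXA was 2.21 ± 0.01 higher in Muscat on the log2 scale (SE, 9 libraries of each type, adjusted p = 9.45e-25), while LOX (-1.96 ± 0.02) and ADH2 (-1.88 ± 0.02) were lower. HT5 (-2.22 ± 0.02) was lower and HT6 (1.31 ± 0.02) higher. PIP2;3 (1.91 ± 0.03) and PIP2 (1.86 ± 0.05) were higher among aquaporins, of which 6 were higher and 4 lower. TIP1;1 (-1.36 ± 0.05) and TIP2;1 (-1.33 ± 0.04) lay at the lower end. MYBPA1 (-1.88 ± 0.05), BCH1 (-1.72 ± 0.05) and MYB14 (-1.62 ± 0.03) were lower, and ZEP (1.42 ± 0.03), LOC100853472 (1.39 ± 0.03) and CTR2 (1.14 ± 0.08) higher.

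The stilbene and phenylpropanoid list was lower in Muscat on average, all 6 genes (camera adjusted p = 0.00245, and adjusted p = 0.0903 with an estimated correlation). So was the pathogenesis-related list, 12 lower and 3 higher of 16 (adjusted p = 0.000454, and adjusted p = 0.0903 with an estimated correlation). In it PR10.4 (-3.05 ± 0.04) and G1 (-3.02 ± 0.03) stood against PR10.5 (1.85 ± 0.03) and PR10.7 (1.11 ± 0.07). The lipoxygenase and alcohol dehydrogenase list was also lower, 6 lower and 2 higher of 8 (adjusted p = 0.0478, and adjusted p = 0.153 with an estimated correlation). Of 29 mitochondrion-encoded genes, 16 were higher and 2 lower (adjusted p = 0.743). The unnamed genes with the largest average differences were LOC100259463 (3.93 ± 0.06) and LOC100266415 (3.73 ± 0.07) above, and LOC100854073 (-3.43 ± 0.06) and LOC100233051 (-3.41 ± 0.06) below. The average mixes effects of opposite sign for the 270 genes with 2-fold type effects in both directions. In this average, limma called 13930 genes, 8840 higher and 5090 lower. Of these 1484 reached 2-fold (484 higher, 1000 lower). For 29.1% of genes, the libraries of one type lay wholly above those of the other within each of the 3 stages, in the same direction. Across stages, 54 genes were higher in Muscat by 2-fold or more at each of the 3 stages, where independent lists would share 6.10. Another 305 were lower at each stage, where 9.57 would be shared.

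**Figure D3:**
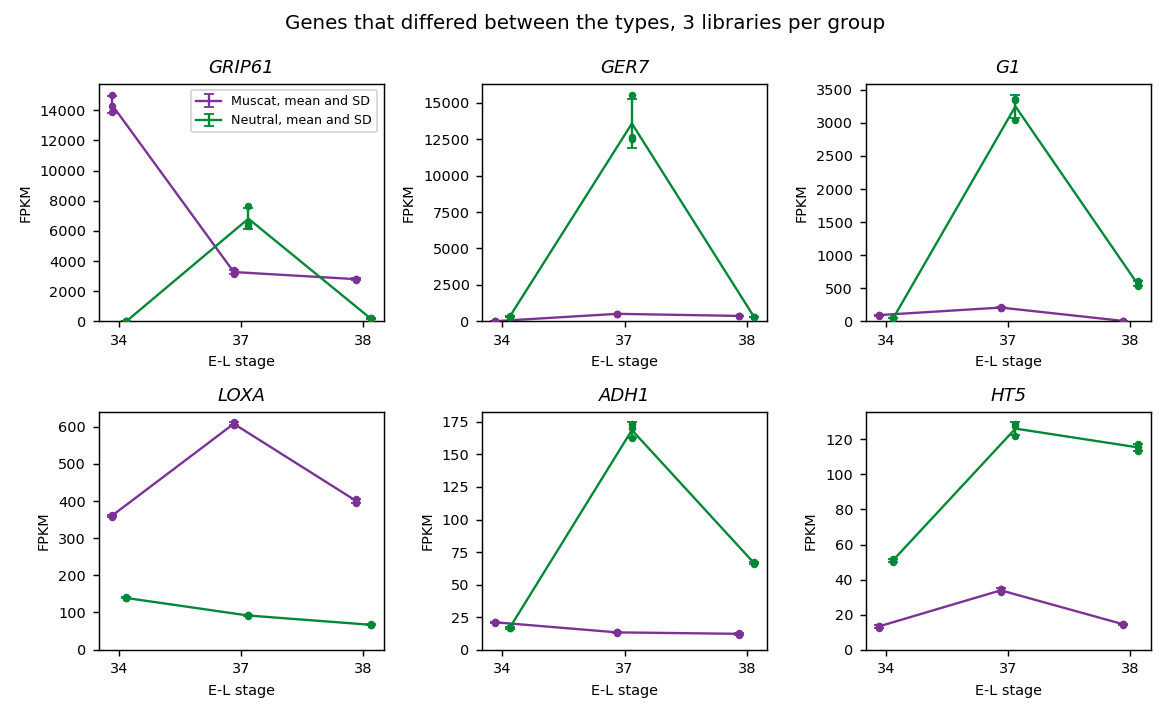
FPKM (linear axis from 0) of GRIP61, GER7, G1, LOXA, ADH1 and HT5 by stage and type, with points for single libraries and lines for group means, and bars that give SD over 3 libraries. LOXA is higher and HT5 lower in Muscat at all 3 stages. GRIP61 is nearly absent in Neutral at E-L 34 only (0.977 FPKM, against 195 in Neutral at E-L 38).

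From E-L 34 to E-L 37 in Muscat, which follows the onset of ripening in this type, anthocyanin genes rose together. GST4, a glutathione transferase for the transport of anthocyanins into the vacuole, rose from 176 ± 4.08 to 1832 ± 189 FPKM (SD, n = 3; log2 change 3.37 ± 0.06, SE, adjusted p = 3.1e-19). UFGT rose from 16.5 ± 0.656 to 151 ± 2.98 FPKM (3.12 ± 0.07). The cell wall invertase CWINV, which splits sucrose, rose from 5.49 ± 0.232 to 58.5 ± 2.96 FPKM (3.20 ± 0.05), and GER7 from 14.5 ± 1.03 to 518 ± 19.96 FPKM (5.07 ± 0.06). BiP (LOC100263033) fell from 114 ± 0.401 to 2.72 ± 0.304 FPKM (-4.95 ± 0.07).

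Of 13 anthocyanin and flavonol genes, 12 rose in Muscat, 9 of them by 2-fold or more, and 1, the transporter ABCC1, fell (-0.35 ± 0.04). This list call held (camera adjusted p = 0.000162, and adjusted p = 0.0208 with an estimated correlation). In the same step 14 of 29 mitochondrion-encoded genes rose and 0 fell (adjusted p = 0.164). Stilbene and phenylpropanoid genes had 5 of 6 members higher at E-L 37 and 0 lower (adjusted p = 0.0225, and adjusted p = 0.111 with an estimated correlation), VINST1 by 2.37 ± 0.08 and LOC100233087 by 1.85 ± 0.06. Aquaporins had 8 of 10 members lower and 1 higher (adjusted p = 0.0158, and adjusted p = 0.21 with an estimated correlation), TIP1;1 by -3.23 ± 0.09 and TIP2;1 by -1.53 ± 0.08. Among regulators, MYB12, an activator of flavonol synthesis, fell from 6.77 ± 0.889 to 0.127 ± 0.0379 FPKM (-2.78 ± 0.08) and MYBPA1 fell (-2.27 ± 0.09). MYC1 (1.96 ± 0.06) and MYBC2-L1 (1.65 ± 0.04) rose, 7 up and 3 down of 10. NCED1 (-2.29 ± 0.06) fell and CCD4b (2.08 ± 0.06) and ZEP (1.33 ± 0.06) rose among carotenoid genes. The sucrose transporter VVSUC27 fell from 17.6 ± 0.465 to 1.17 ± 0.110 FPKM (-3.10 ± 0.09) and SWEET15 (LOC100243643) by -2.42 ± 0.04, whereas HT5 rose (1.3 ± 0.04). CIPK15 (LOC100259329) rose from 7.57 ± 0.670 to 139.8 ± 2.502 FPKM (4.04 ± 0.06). PR10.3 (2.95 ± 0.08) and PR10.7 (2.40 ± 0.12) rose, and the polygalacturonase inhibitor gene LOC100232865 (-2.59 ± 0.04) and CHI4C (-1.83 ± 0.05) fell, with 7 up and 7 down of 16. GRIP68 (-2.38 ± 0.06), GRIP61 (-2.14 ± 0.12), APX (-2.42 ± 0.06), ADH2 (-2.06 ± 0.04) and HSP101 (-1.05 ± 0.05) fell, and GDHB (1.40 ± 0.08) rose. The largest changes of unnamed genes were LOC100253046 (8.34 ± 0.04) and LOC100249717 (5.98 ± 0.07), which rose, and LOC100263637 (-7.09 ± 0.08) and LOC104879540 (-5.42 ± 0.06), which fell. In this step limma called 12519 genes, 6681 up and 5838 down. Of them 2391 moved by 2-fold or more (1167 up, 1224 down), with no overlap of the groups for 83.9% of genes against 10% by chance.

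From E-L 37 to E-L 38 in Muscat, the last step to harvest ripeness, 10 of 16 pathogenesis-related genes fell, and 10 of 13 anthocyanin and flavonol genes rose, UFGT not among them. G1 fell from 209 ± 10.99 to 7.59 ± 0.265 FPKM (SD, n = 3; log2 change -4.61 ± 0.06, SE, adjusted p = 2.88e-20). LOXO fell from 191 ± 5.19 to 37.1 ± 0.729 FPKM (-2.34 ± 0.03). The flavanone hydroxylase F3H rose from 80.7 ± 2.23 to 160.2 ± 4.72 FPKM (0.98 ± 0.04) and FLS1 by 0.74 ± 0.07. TIP1;1 rose from 2.62 ± 0.378 to 13.8 ± 0.955 FPKM (2.03 ± 0.09) and GRIP68 from 143 ± 3.16 to 574 ± 19.4 FPKM (2.0 ± 0.06).

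Anthocyanin and flavonol genes had 10 of 13 members higher at E-L 38 and 0 lower (camera adjusted p = 0.0201, and adjusted p = 0.0932 with an estimated correlation). Stilbene and phenylpropanoid genes had 5 of 6 lower and 0 higher (adjusted p = 0.00881, and adjusted p = 0.0932 with an estimated correlation), with LOC100233087 down by -2.07 ± 0.06. Of the pathogenesis-related genes, 10 of 16 fell and 2 rose (adjusted p = 0.00371, and adjusted p = 0.111 with an estimated correlation), PR10.4 by -1.85 ± 0.08. In the MLO family, membrane proteins known for a role in powdery mildew susceptibility, 5 of 7 fell and 2 rose (adjusted p = 0.0142, and adjusted p = 0.0932 with an estimated correlation), LOC100267554 by -1.44 ± 0.03 and MLO15 by -1.20 ± 0.03. Of 29 mitochondrion-encoded genes, 1 rose and 6 fell (adjusted p = 0.167), and 0 passed when adjusted over the list alone. LBCY1 (LOC100246737), a lycopene cyclase gene, rose by 1.83 ± 0.06, MADS5 by 1.80 ± 0.08, CTR2 by 1.36 ± 0.13, SWEET15 by 1.06 ± 0.04 and MADS3 by 1.03 ± 0.11. HT5 (-1.17 ± 0.04) and TIP1;2 (-1.02 ± 0.06) fell. The unnamed LOC100263489 (6.29 ± 0.09) and LOC100254843 (5.73 ± 0.14) rose, and LOC100247990 (-5.23 ± 0.08) and LOC100267145 (-4.50 ± 0.07) fell. For this step limma called 10250 genes, 7006 up and 3244 down. Of them 839 moved by 2-fold or more (328 up, 511 down), with no overlap for 71.9% of genes against 10% by chance. After scaling to a common upper quartile, 9298 genes passed, 5414 up and 3884 down, so that the share of rises went from 68.4% to 58.2%.

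From E-L 34 to E-L 37 in Neutral, GRIP61 rose from 0.977 ± 0.549 to 6812 ± 703 FPKM (SD, n = 3; log2 change 11.78 ± 0.12, SE, adjusted p = 3.52e-22). G1 rose from 48.9 ± 2.77 to 3249 ± 173 FPKM (6.03 ± 0.06), GER7 from 330.0 ± 7.57 to 13567 ± 1699 FPKM (5.35 ± 0.06) and ADH1 from 16.8 ± 0.640 to 169 ± 5.80 FPKM (3.25 ± 0.04). VINST1, a stilbene synthase gene, rose from 8.32 ± 0.652 to 81.6 ± 6.03 FPKM (3.15 ± 0.08). PR10.7 fell from 39.3 ± 1.99 to 1.19 ± 0.554 FPKM (-4.23 ± 0.12).

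Anthocyanin and flavonol genes were split in this step, with 6 of 13 higher and 6 lower (camera adjusted p = 0.662, fry adjusted p = 1.12e-07). GST4 (1.45 ± 0.06) and CHS3 (1.34 ± 0.04) rose, and CHS1 (-1.22 ± 0.06) and CHS2 (-1.11 ± 0.05) fell. Plastid-encoded photosynthesis genes rose, 13 of 14 with 0 falling (adjusted p = 0.00881, and adjusted p = 0.0882 with an estimated correlation). They rose in the other steps as well without a camera call, 12 of 14 and 13 of 14 in the Muscat steps with 0 falling, and 11 with 2 falling from E-L 37 to E-L 38 in Neutral. ViviCp008 rose by 1.60 ± 0.17 and ViviCp079 by 1.06 ± 0.11. Only 14 of the 45 plastid-encoded photosynthesis genes measured reached the expression minimum. As 3 libraries suffice for it, a scarce gene could pass through a later stage alone, which favours rises. Plastid-encoded genes are scarce in the libraries. All of them together, beyond this list, took 0.0025% to 0.0028% of FPKM in Neutral E-L 34 and 0.0075% to 0.0099% in Neutral E-L 37. Of 29 mitochondrion-encoded genes, 13 rose and 3 fell (adjusted p = 0.162). Aquaporins had 7 of 10 lower and 2 higher (adjusted p = 0.164), with TIP1;1 (-2.67 ± 0.09) and PIP1;1 (-1.94 ± 0.10) down and PIP2;2 (1.57 ± 0.03) up. MYB12 (-3.02 ± 0.08), LAR2 (-2.28 ± 0.07), MYC1 (-1.36 ± 0.06), GA2ox6 (-3.19 ± 0.07), VVSUC27 (-2.07 ± 0.09), MFT (-2.69 ± 0.08) and VFUL-L of the MADS-box list (-1.83 ± 0.11) fell. PR10.3 (3.45 ± 0.08), CIPK16 (1.90 ± 0.06), MLO6 (1.85 ± 0.04), LOC100245997 (PAL, 1.75 ± 0.06), NCED2 (1.28 ± 0.07) and the malic enzyme gene VVME2 (1.13 ± 0.04) rose. Of unnamed genes, LOC100242852 (7.92 ± 0.08) and LOC100247990 (6.10 ± 0.08) rose and LOC100245734 (-7.77 ± 0.05) and LOC100256023 (-5.57 ± 0.21) fell. The count by limma was 13199 genes, 5521 up and 7678 down. Of them 2737 moved by 2-fold or more (975 up, 1762 down), with no overlap for 78.5% of genes against 10% by chance. After scaling to a common upper quartile, 6402 rose and 6729 fell, and at 2-fold 1209 rose and 1500 fell, so most of the excess of falls depends on the scaling.

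From E-L 37 to E-L 38 in Neutral, all 13 anthocyanin and flavonol genes rose, 9 of them by 2-fold or more. This list call held (camera adjusted p = 0.000317, and adjusted p = 0.0208 with an estimated correlation). In the same step 16 of 29 mitochondrion-encoded genes rose and 2 fell (adjusted p = 0.435). F3H rose from 26.8 ± 1.39 to 299 ± 5.45 FPKM (SD, n = 3; log2 change 3.43 ± 0.04, SE, adjusted p = 5.01e-21) and CHS2 (LOC100232843) from 72.9 ± 7.70 to 390.1 ± 4.01 FPKM (2.41 ± 0.05). GER7 fell from 13567 ± 1699 to 306 ± 6.42 FPKM (-5.46 ± 0.06), GRIP61 from 6812 ± 703 to 195 ± 4.82 FPKM (-5.12 ± 0.12) and GRIP68 from 635 ± 75.7 to 50.8 ± 0.498 FPKM (-3.61 ± 0.06).

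Lipoxygenase and alcohol dehydrogenase genes had 6 of 8 lower at E-L 38 and 1 higher (adjusted p = 0.0472, and adjusted p = 0.129 with an estimated correlation), ADH1 by -1.33 ± 0.04. MLO genes had 6 of 7 lower and 1 higher (adjusted p = 0.0278, and adjusted p = 0.111 with an estimated correlation), MLO7 by -1.55 ± 0.08. CWINV (1.99 ± 0.05), MYC1 (1.86 ± 0.06), 4CL (1.66 ± 0.06), LBCY1 (1.60 ± 0.06), GA20ox1 (LOC100257500, 2.52 ± 0.12), CTR2 (2.16 ± 0.13), PR10.7 (2.60 ± 0.12) and PR1 (2.57 ± 0.10) rose, and CIPK15 rose by 3.12 ± 0.06. CIPK08 (-3.23 ± 0.06), TIP1;1 (-2.99 ± 0.09), VVSUC27 (-2.53 ± 0.09), G1 (-2.52 ± 0.06), MYBPA1 (-2.39 ± 0.09), APX (-1.94 ± 0.06), the neutral invertase NIN1 (-1.88 ± 0.05), NCED2 (-1.86 ± 0.07) and MADS3 (-1.69 ± 0.11) fell. Of unnamed genes, LOC100245734 (7.13 ± 0.05) and LOC100256023 (4.64 ± 0.21) rose, and LOC100261940 (-7.68 ± 0.09) and LOC109123939 (-5.26 ± 0.25) fell. By limma, 13147 genes passed, 8015 up and 5132 down. Of them 2589 moved by 2-fold or more (1271 up, 1318 down), with no overlap for 81.8% of genes against 10% by chance. Scaling to a common upper quartile gave 7028 rises and 5960 falls, and at 2-fold 990 rises and 1534 falls.

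**Figure D4:**
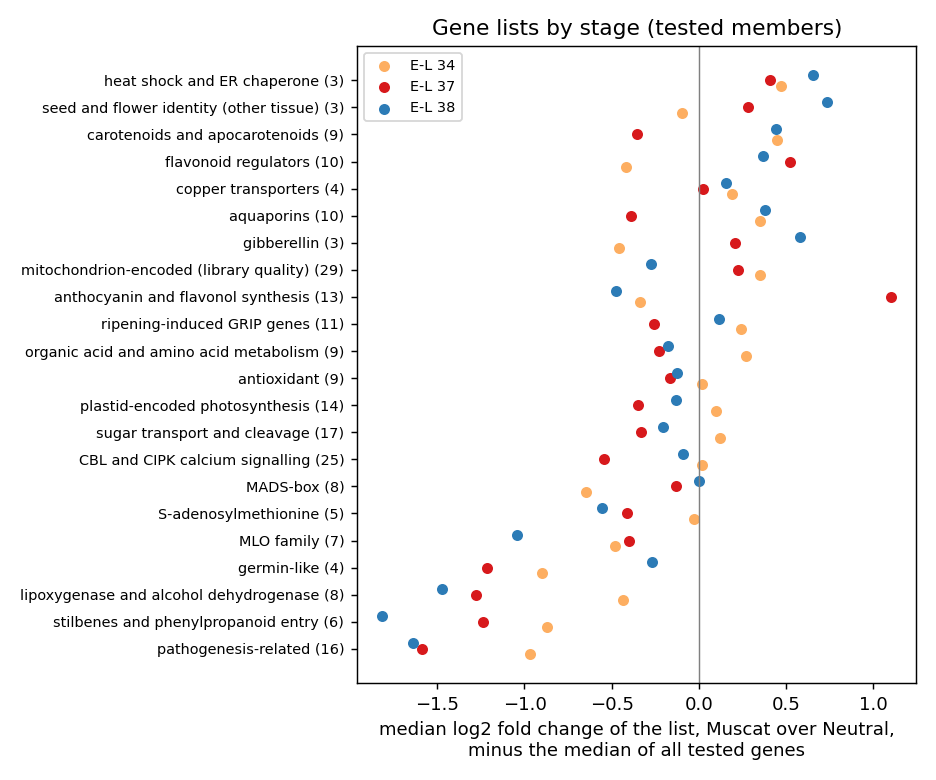
Gene lists in the comparison of Muscat with Neutral at each stage. Each point is the median log2 difference of the genes of a list, relative to the median of all genes. The pathogenesis-related list lies below all genes at each stage, and lowest at E-L 38 (-1.64).

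The stage course was set against the type by the interaction test, which asks whether the changes between stages differed between Muscat and Neutral. It called 14843 of 15981 genes by limma's F-test, 5027 of them with an interaction of 2-fold or more. For 270 genes the type effect was 2-fold or more in opposite directions at different stages. GRIP61, GER7 and G1 were among the genes called (adjusted p = 2.21e-20, 8.71e-19 and 2.21e-20), and so were UFGT (3.28e-15), CWINV (4.21e-17) and TIP1;1 (2.2e-16). GST4 rose by 3.37 ± 0.06 and then 0.42 ± 0.06 in Muscat and by 1.45 ± 0.06 and then 1.5 ± 0.06 in Neutral (SE, n = 3 libraries per group; interaction adjusted p = 4.64e-13). F3H rose by 1.78 ± 0.04 and 0.98 ± 0.04 in Muscat and by 0.31 ± 0.04 and 3.43 ± 0.04 in Neutral (adjusted p = 1.46e-16). From E-L 34 to E-L 37, 215 genes rose and 469 fell by 2-fold or more in both types, where independent lists would share 71.2 and 135. In that step 125 rose in Muscat and fell in Neutral and 67 the reverse, against 129 and 74.7. From E-L 37 to E-L 38, 79 rose and 184 fell in both, against 26.1 and 42.1. In this later step 66 rose in Muscat and fell in Neutral, against 27.1, and 35 did the reverse, against 40.6.

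Of all lists, camera called 10 of 88 tests in the type comparisons and 11 of 88 in the stage comparisons, over 22 lists and 4 comparisons each. With an estimated correlation 0 and 2 remained below the threshold, both for anthocyanin and flavonol genes from E-L 34 to E-L 37 in Muscat and from E-L 37 to E-L 38 in Neutral. By fry, which tests whether the genes of a list move on balance one way without comparing them with other genes, 74 and 77 tests passed. The lists of copper transporters, organic acid and amino acid metabolism, S-adenosylmethionine, antioxidant, gibberellin, germin-like, heat shock and ER chaperone, flavonoid regulator, sugar transport, carotenoid, ripening-induced GRIP, seed and flower identity and mitochondrion-encoded genes were called by camera in 0 comparisons. Of the sesquiterpene synthase genes with a symbol, 2 were in the table and 0 reached the expression minimum.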

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

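The interaction test behind these values was fixed beforehand. The stricter choice of genes with 2-fold effects in opposite directions, the 2 tests of ripening progress, the test of scaling and the test of exchanged labels on genes outside the pattern were chosen only after the result was seen. Of 121 genes named in the type comparisons, 120 pass the interaction test, so passing it is common here. Given below are the 15 genes in a list, of 22, whose type effect is 2-fold or more in opposite directions at 2 stages. Values are the interaction adjusted p by limma and the log2 differences of Muscat from Neutral at the 3 stages in order.

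In flavonoid and phenylpropanoid synthesis, what stands out is a type effect that changes sign with stage for UFGT (3.28e-15, with -2.02, 1.45 and -0.35), CHS2 (LOC100232843, 3.27e-17, with -1.55, 1.97 and -0.24), the regulator MYC1 (1.59e-16, with -1.41, 1.91 and -0.33) and 4CL (3.17e-14, with -1.10, 1.08 and -0.62). CWINV went the same way (4.21e-17, with -1.87, 1.70 and -0.34). Lower at E-L 34 and higher at both later stages were GA2ox6 (LOC100258946, 1.25e-16, with -2.23, 2.02 and 0.80) and PR10.7 (5.03e-16, with -2.0, 4.64 and 0.69). The aquaporin genes TIP1;1 (2.2e-16, with -2.66, -3.22 and 1.81) and PIP2;2 (2.45e-18, with 1.38, -1.39 and 0.34) also change sign between stages, both lower in Muscat at E-L 37 and higher at E-L 38. CCD4b (LOC100252859, 2.72e-16, with -1.09, 0.54 and 2.55), CIPK08 (2.7e-16, with -1.75, -1.57 and 1.15) and GDHB (7.18e-14, with -1.75, -0.06 and 1.40) go from lower to higher in Muscat. TL1 (1.91e-16, with 1.08, -1.52 and 0.52), GRIP68 (1.61e-19, with -0.80, -2.14 and 3.47) and GRIP61 (2.21e-20, with 12.86, -1.05 and 3.84) complete the list.

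A separate pattern concerns the step at which genes rose: genes that rose 2-fold or more from E-L 34 to E-L 37 in Muscat rose in Neutral 426 times from E-L 37 to E-L 38 (92.8 for independent lists) and 215 times from E-L 34 to E-L 37 (71.2), a ratio of 1.98, or 1.52 relative to the independent lists. Falls were shared 490 and 469 times (101 and 135), a ratio of 1.40 relative to independent lists. After scaling to a common upper quartile the ratio of rises was 1.54 (367 and 239), or 1.88 relative to independent lists, so scaling does not remove the shift. Falls were then shared 548 and 447 times, with a smaller ratio of 1.20 relative to independent lists. An exchange of the E-L 37 and E-L 38 labels in Neutral is unlikely if both types change alike in that step, which holds only in part (66 genes rose 2-fold in Muscat and fell in Neutral, 27.1 for independent lists), since of 446 genes changed 2-fold in the later Muscat step alone 26.7% went the other way in Neutral (24.9% of 438 after scaling), whereas tests on genes that belong to the pattern decide nothing (16.1% of 31 genes lower at Neutral E-L 38, and 0.43 of the Neutral path covered by E-L 37 along the Muscat change, 2391 genes). Along the change of Neutral itself (4708 genes), Muscat stood at 0.426, 0.841 and 0.919 at the 3 stages and Neutral at 0, 0.519 and 1. These genes were chosen for their change in Neutral, which sets Neutral at 0 and 1 and may by itself make the Muscat path shorter. By E-L 37 Muscat had covered 0.843 of its own path and Neutral 0.519, a difference of 0.324. Slower ripening progress in Neutral could give this difference, as could a Muscat skin already further along at E-L 34, but along the Muscat change Neutral E-L 34 stood at 0.0477 over all genes, ahead for those that rose (0.245) and behind for those that fell (-0.126), and the tables do not decide between them.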

How the results depend on the processing

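The alternatives were chosen beforehand, and which of them to discuss was chosen only after the result was seen. Of 58 alternatives, 49 kept their count within 1.5 times, and 9 did not. A 2-fold minimum, which keeps fewer genes by its construction, left 2536, 3133, 2012 and 1484 genes for the type comparisons at E-L 34, E-L 37, E-L 38 and on average, 2391 and 839 for the Muscat steps, and 2737 and 2589 for the Neutral steps. The gene lists went from 21 camera calls to 2 with an estimated correlation. The estimate lay below the preset 0.01 for the anthocyanin (-0.00048), stilbene (0.0078), lipoxygenase (-0.089), MLO (-0.073) and plastid (-0.028) lists. A higher correlation therefore cannot explain the calls lost there. It lay above 0.01 for the pathogenesis-related (0.060), calcium signalling (0.046), aquaporin (0.115) and MADS-box (0.204) lists. The cause of the losses was not tested further. Leaving out 1 library gave, over 78 fits, 12344 to 12606, 12927 to 13269, 11414 to 11548 and 13754 to 14021 genes for the type comparisons, 11991 to 12107 and 9396 to 9589 for the Muscat steps, 12889 to 13115 and 12715 to 13128 for the Neutral steps, and 14664 to 14920 for the interaction. All 372 named calls of 2-fold or more kept their side of the threshold and their sign under a pseudocount of 0.1, without a minimum, after upper-quartile scaling and with the block, 333 of 333 did so in the groups compared alone, and 0 were reversed in any setting. Changes of this size could hardly be lost, and named calls of less than 2-fold were not in this check.

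With the replicate number as a block, the pairing of libraries by number gave 12793, 13276, 11947 and 13901 genes for the type comparisons, 12492, 10168, 13191 and 13115 for the stage steps and 14826 for the interaction. The numbers do not pair the libraries: over 45 pairs of equal number the median residual correlation was -0.00718, and 7 of 18 libraries were nearest to their own number. Depth of at least 15.3 M fragments limits scarce genes, of which 5030 to 6486 per library are listed at 0.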

Other observations

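The genes in the first 2 paragraphs, the depth test for GRIP61 and the verdict on its genotype test were chosen only after the result was seen. CHLH, a subunit of magnesium chelatase in chlorophyll synthesis, had 30.3 ± 0.592 FPKM (SD, n = 3) in Muscat and 3.84 ± 0.339 in Neutral at E-L 37 (log2 difference 2.70 ± 0.05, SE), and 25.7 ± 0.204 against 5.36 ± 0.151 FPKM at E-L 38 (2.07 ± 0.05). PSBP1, of the oxygen-evolving complex of photosystem II, was higher by 1.57 ± 0.04 and 1.89 ± 0.04 at these stages, and PSBP2 by 0.34 ± 0.11 and 1.34 ± 0.11. Plastid-encoded photosynthesis genes had 2 higher and 4 lower of 14 at each of them (camera adjusted p = 0.547 and 0.592). THI1-1, a gene of thiamine synthesis, had 1347 ± 22.2 against 221 ± 23.8 FPKM at E-L 37 (2.61 ± 0.05).

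The regulator gene MYB24 rose in both types from E-L 34 to E-L 37 and then in Muscat alone, to 39.0 ± 0.882 FPKM (SD, n = 3) against 5.10 ± 0.382 in Neutral at E-L 38 (log2 difference 2.71 ± 0.08, SE). CBF4, a regulator of cold response, fell to 16.8 ± 1.81 FPKM in Muscat at E-L 38, against 219 ± 3.41 in Neutral (-3.64 ± 0.06). PL1 had 152 ± 2.73 against 19.8 ± 0.497 FPKM at E-L 38 (2.88 ± 0.06).

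GRIP61 was nearly absent in Neutral E-L 34, with 1.61, 0.63 and 0.69 FPKM in the 3 libraries, and abundant in the other 5 groups. Fewer fragments in these libraries are unlikely to be the cause, as the ratio of group means is 14741 and that of depths 2.22. Whether reads were given to 1 other gene cannot be told from these values. LOC100260685 gains 7947 FPKM there, 55.2% of the 14396 that GRIP61 lacks, which meets the bound set beforehand. However, it was picked as the highest gain of any gene. FPKM is also divided by gene length, so a share of FPKM is not a share of reads. LOC100260685 is also higher in Neutral at E-L 37, where GRIP61 is higher too, so this stays open. Plants of another genotype behind the Neutral E-L 34 samples were to show as genes off in that group alone, and there were 0, against 3 in Muscat E-L 38 and 1 in Muscat E-L 34. The bound written beforehand is met, also with GRIP61 itself counted (1 against 3), but counts this small differ by no more than their spread (binomial p = 0.25 for 0 against 3 and 0.625 for 1 against 3), so the verdict, changed after the value was seen, is that this stays open.

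The 359 genes that differed 2-fold or more between the types in 1 direction at all 3 stages stand near each other in the gene order, with 3.47 times the pairs of permuted orders at 1 to 5 genes apart and 1.3 times at 6 to 25. Parental haplotypes that differ between the Muscat and the Neutral samples might give such an excess over long distances, and neighbouring copies of a gene family over short ones only. At 26 to 100 genes apart the ratio was 1.14, with 8 of 1000 permutations as high, which lies between the bounds set for both. Genes that changed with stage in both types (887) had 2.27 at 1 to 5 apart and 1.1 at 26 to 100, so neighbourhoods of co-expressed genes in general remain possible, and all 3 explanations stay open. The densest stretch of 100 genes holds 15 of the type genes, 14 of them lower in Muscat. A smaller set of permuted orders reached 12. Permuting also breaks up the excess at 1 to 5 genes apart, so this count is not separate from it. VINST1, CBF4 and TFL1C are the genes with a symbol in this stretch, whether or not they are type genes.

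Libraries were also regrouped at random. For each comparison of 3 against 3 libraries there are 10 splits, too few for a share under 0.05: the real split was the 1 with the most genes, 12790, 13306 and 11964 for the type at the 3 stages and 12519, 10250, 13199 and 13147 for the stage steps, and the highest other split had 1 gene at E-L 34 and 0 in each other case. For the average over stages, 1 of 100 splits, the real one, had as many as 13930 genes, and the highest other had 6291. For the interaction, 1 of 100 had as many as 14843, and the highest other had 10660. The replicates of a group are close and the groups lie apart, so splits that mix groups were likely to call fewer genes. These 2 counts (1 of 100 splits for each) therefore show only that libraries of the same group resemble each other. The spread of replicates may be technical, and the splits exclude no chance in the choice of plants or harvests.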
